A study of Mus musculus with 9 samples.

How the data were processed

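The series holds 9 libraries of sorted PancOVA tumour cells, 3 each after co-culture with iCAF, myCAF or qPSC fibroblasts, and the groups and replicate numbers were taken from the sample titles. Per the labels' protocols, stellate cells were embedded in matrigel and kept quiescent, and those of the iCAF and myCAF groups were primed for 48 h. All were co-cultured with dye-labelled tumour cells for 48 h. The droplets were then dissolved with collagenase and the dye-positive cells were sorted after staining for CD90.1. Per the labels' protocols, libraries were made with a stranded mRNA kit and sequenced as single reads of 50 bases.

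The authors deposited 1 table of TPM values for 41457 genes, named by symbol, that sum to 1000000 in each library. Per the submitters' processing notes, Salmon, R 4.0.1 and DESeq2 were used, with no step named for each. The genome build and annotation are not given in the sources used here. TPM corrects for gene length and total, so a library whose composition differs shifts all its other genes. Of the symbols, 98.9% matched a single gene model of GENCODE M21 (GRCm38), which gave exon lengths and coordinates. TPM times exon length came in whole multiples of 1 constant per library for 97.8% to 98.05% of genes under 200 reads, within a tolerance of 0.05 reads. The constants implied 38870594 to 45317253 reads per library, which served for depth and for limma-voom as an alternative.

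Genes with at least 1 TPM in at least 3 libraries were kept, 11704 in all, and log2(TPM + 1) values were fitted with limma 3.58.1 in R 4.3.3, with a mean-variance trend and all 9 libraries in 1 fit by group. Fold changes are on the log2(TPM + 1) scale, which understates those of low genes, and errors of fold changes are standard errors. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. The design fixed before the data were examined put a count model first and this fit second, for a table of normalized values. The values turned out to be TPM, so the second was used.

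Of 39 gene lists fixed before the data were examined, 38 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, adjusted over the lists. No list passed in any comparison with an estimated correlation, where the lowest adjusted p was 0.40 for iCAF against qPSC, 0.18 for myCAF against qPSC and 0.65 for iCAF against myCAF. With fry, which asks whether the genes of a list move on balance one way, 13, 0 and 9 lists passed in the same order. Lists share members, and 5 of the 15 tested fibroblast genes belong to another list too.

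A rule fixed before the data were examined chose genes to be named in each comparison. It took, per comparison, the 8 largest changes in each direction among called genes with at least 5 TPM in the higher group and no overlap of replicates, and up to 4 called members of each list. It always took a fixed set of marker genes and, with fewer than 5 calls, the 10 smallest p-values. Symbols that mark unnamed gene models were left out. Genes named outside this rule, such as those named only for a call without iCAF replicate 3, were chosen after their values were seen.

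On simulated data for iCAF against qPSC with 50 changed genes per size, the procedure recovered 80% of 1.5-fold and 100% of 2-fold changes when libraries were alike. With iCAF replicate 3 deviating as observed, it recovered 22% of 1.5-fold, 80% of 2-fold, 98% of 3-fold and 100% of 4-fold changes. Unchanged genes called were 14 of 11569 tested genes when libraries were alike and 2 of 11570 in the other setting. The simulation gave every gene the same relative spread and shifted no library other than iCAF replicate 3. Its shares therefore do not carry over to the real data, where recovery may be lower. There Tgtp1, 2.57-fold lower in myCAF than in qPSC libraries, did not pass (limma, adjusted p = 0.0683). Libraries of a group correlated at r from 0.980 to 0.997, and the lowest chi-square per degree of freedom between 2 libraries of a group was 8.08 on the implied reads, so no library was a copy of another within sampling noise.

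The alternatives were other centring, filters and pseudocounts, only the 6 libraries of a comparison, a replicate block, limma without the trend, a fold threshold and each library left out in turn. Added after seeing the data were limma-voom on the implied reads, removal of the gene-length trend, and combinations of leaving out iCAF replicate 3 with these, with the block, with centring and with the fibroblast index as a covariate. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared tables and figures.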

Results

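Messenger RNA was sequenced from PancOVA cells, a mouse pancreatic tumour cell line, after 48 h of co-culture in matrigel with pancreatic stellate cells in 1 of 3 states. The stellate cells, fibroblasts of the pancreas, had been kept quiescent (qPSC), primed with TGF-β1 at 2 ng/ml towards a myofibroblast-like state (myCAF), or primed with medium conditioned by Tc17 cells, a class of T cells, towards an inflammatory state (iCAF). The tumour cells carried a proliferation dye and were sorted by it, so the libraries were meant to hold tumour cells and not fibroblasts. Each of the 3 groups had 3 libraries, and the qPSC co-cultures were the background control. Values were TPM (transcripts per 1000000 transcripts), and the steps between low values implied 38870594 to 45317253 reads per library. Nothing in the labels says whether the replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical.

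The sorted cells had the transcripts of keratin-expressing cells with little expression of classical epithelial adhesion genes. Krt8, a keratin of simple epithelia, lay at 784 ± 10.8 TPM (SD, n = 3) in qPSC, 771 ± 25.7 in iCAF and 819 ± 9.24 in myCAF libraries. Vim, an intermediate filament gene of mesenchymal cells, lay at 2911 ± 135, 3185 ± 36.7 and 3142 ± 71.4 TPM in the same order. Epcam and Cdh1, which encode epithelial adhesion proteins, were listed at 0 in all 3 qPSC libraries and did not exceed a mean of 0.0092 TPM in another group, too low to be tested. Neither Krt8 nor Vim passed the test in a comparison (limma, adjusted p from 0.32 to 1).

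Transcripts of many fibroblast marker genes were present in every library and differed between them, while others were nearly absent. Col1a1, which encodes a chain of type I collagen, lay at 60.6 ± 8.30 TPM in qPSC, 49.6 ± 22.2 in iCAF and 127 ± 50.8 in myCAF libraries (SD, n = 3). Thy1, which encodes the CD90 antigen used to stain the fibroblasts, lay at 4.08 ± 1.295, 2.61 ± 0.748 and 6.85 ± 3.12 TPM. Both belong to a fixed list of 18 fibroblast genes. Another member, Col1a2, which encodes the other chain of type I collagen, lay at 0.219 ± 0.0342, 0.189 ± 0.0139 and 0.243 ± 0.0336 TPM, and with Lum and Fap it failed the expression filter. The mean log2(TPM + 1) over the 15 that passed, called the fibroblast index here, was 4.72 ± 0.191 in qPSC, 3.83 ± 0.463 in iCAF and 5.13 ± 0.571 in myCAF libraries. In an exact two-sided permutation test of the index, p was 0.1 for iCAF against qPSC, 0.1 for iCAF against myCAF and 0.4 for myCAF against qPSC, where 0.1 is the smallest p that 3 against 3 libraries allow. Of 16 leukocyte genes, 3 passed the expression filter, too few for a test of the list, and no member passed the gene test in a comparison, with or without iCAF replicate 3.

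One library stood apart from the other 8. In iCAF replicate 3, genes of ribosomal proteins took 21.9% of all TPM, against 14.7% to 15.6% in the other 8 libraries. Its median log2 TPM over the tested genes was 3.96, against 4.35 to 4.47. Mki67, a gene of dividing cells, lay at 44.0 TPM in it and at 87.5 and 118 TPM in the other iCAF libraries. The first principal component, with 60.2% of the variance, placed it at -55.7, while the other 8 libraries lay between -8.94 and 15.8. Main values below include this library. The numbers of genes called over all genes, in total and in the lists, are also given without it. Leaving out each library in turn was planned before the data were examined, but this one was singled out after its deviation was seen.

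**Figure D1:**
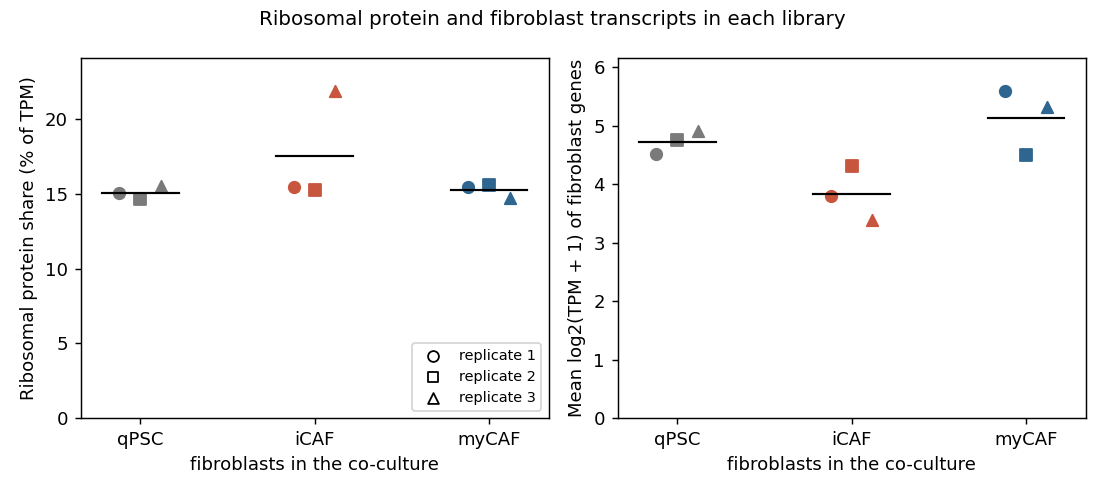
Share of TPM in ribosomal protein genes (left, percent) and mean log2(TPM + 1) of 15 fibroblast genes (right) in each library, by the fibroblasts in the co-culture. Points are libraries and bars are group means; iCAF replicate 3 lies at 21.9% on the left, and the myCAF mean of 5.13 lies above the iCAF mean of 3.83 on the right.

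The first comparison asked how tumour cells differed after co-culture with inflammatory fibroblasts from those with quiescent ones. Interferon-stimulated genes were lower after iCAF co-culture. Cxcl10, which encodes a chemokine that attracts T cells, lay at 66.4 ± 2.02 TPM in iCAF and 230 ± 17.8 TPM in qPSC libraries (SD, n = 3), a log2 fold change of -1.78 ± 0.16 (SE), or 3.43-fold lower (limma, adjusted p = 0.0112). The antiviral genes Rsad2, Ifit1 and Mx1 were 2.53-, 2.34- and 3-fold lower, each with the same limma adjusted p of 0.0112. Of 25 tested interferon-response genes, 10 were lower and 0 higher (15 and 0 without iCAF replicate 3). When adjusted over the list alone 24 were lower, and all 25 had a negative fold change. The median log2 fold change of the list was -0.83, where the median of all genes was -0.15 (camera, adjusted p = 2.1e-21, but adjusted p = 0.40 with an estimated correlation). By fry, which sets the list against no change and not against the other genes, the adjusted p was 0.012. Across all 11704 tested genes, 70 were lower and 0 higher in iCAF than in qPSC libraries by limma, while 1851 had an unadjusted p under 0.05. Cxcl10 lies on chromosome 5 from 92346638 to 92348889 and Ifit1 on chromosome 19 from 34640871 to 34650009 in GENCODE M21 (GRCm38).

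Among the called genes with the largest fold changes were also Ifi206, another chemokine gene and 2 nuclear receptor genes of the Nr4a family. Ifi206, of the Ifi200 family of DNA-binding proteins, was 4.12-fold lower (30.52 ± 1.07 TPM in qPSC, 7.11 ± 3.59 in iCAF; limma, adjusted p = 0.0146). Nr4a3 and Nr4a2, nuclear receptors induced early after stimulation, were 4.84-fold lower (adjusted p = 0.0383) and 3.14-fold lower (adjusted p = 0.0338) by limma. Ccl5, another chemokine of T cells, lay at 157 ± 55.2 TPM in qPSC and 48.0 ± 10.7 TPM in iCAF libraries, 3.15-fold lower (limma, adjusted p = 0.0240). Usp2, a deubiquitinase gene, and Gfra1, a receptor gene for GDNF, were each 2.72-fold lower but lay under 6 TPM in both groups (limma, adjusted p = 0.0410 and 0.0465).

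**Figure D2:**
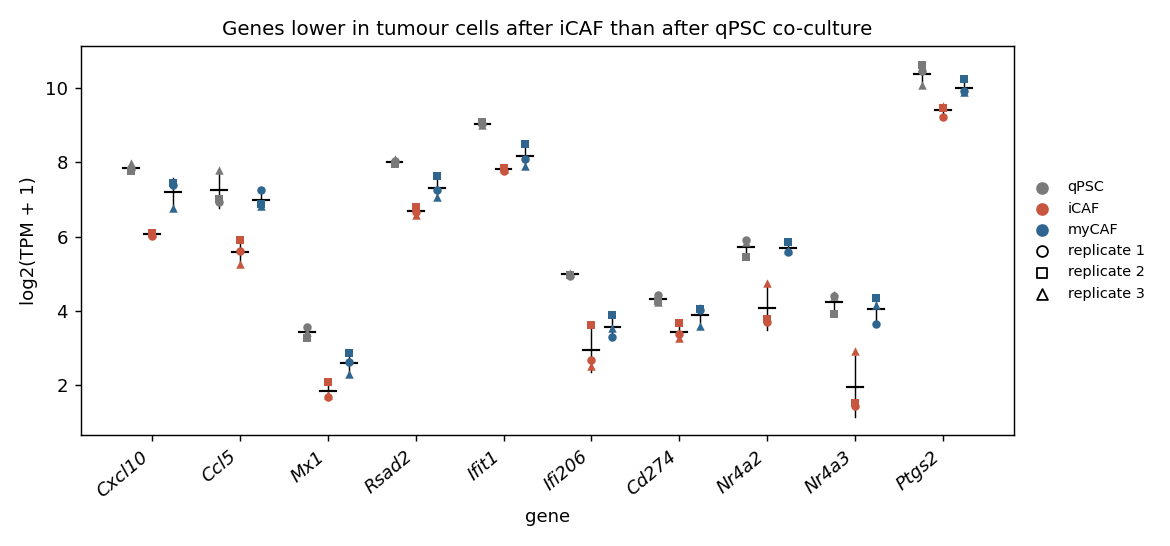
Expression of 10 genes called lower in iCAF than in qPSC libraries, as log2(TPM + 1) on the vertical axis for each gene on the horizontal axis. Points are libraries, short bars are group means and vertical lines are ± 1 SD of 3 libraries; the 3 iCAF libraries lie below the 3 qPSC libraries for Cxcl10 (66.4 against 230 TPM on average).

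Inflammatory gene groups were lower too. The median log2 fold change of all genes in this comparison was -0.15, and -0.03 without iCAF replicate 3. Medians, signs and counts over a list alone in this comparison include that shift. Of 19 NF-κB response genes, 3 were lower and 0 higher (5 and 0 without iCAF replicate 3), with 11 lower when adjusted over the list alone and a median log2 fold change of -0.34 (camera, adjusted p = 6.6e-07; adjusted p = 0.40 with an estimated correlation). The 3 were Cxcl10, Ccl5 and Ptgs2, and Ptgs2, which encodes cyclooxygenase-2, lay at 1353 ± 244 TPM in qPSC and 677 ± 69.6 TPM in iCAF libraries (limma, adjusted p = 0.0274). Of 21 chemokine and cytokine genes, 2 were lower, Cxcl10 and Ccl5 (4 without iCAF replicate 3), with 8 lower when adjusted over the list alone and all 21 negative (camera, adjusted p = 1.7e-06; adjusted p = 0.40 with an estimated correlation). In the list of 17 genes that respond to IL-17, of which 11 belong to other lists too, Nfkbiz was lower (2 genes without iCAF replicate 3), 8 were lower when adjusted over the list alone, and the median was -0.39 (camera, adjusted p = 0.00041; adjusted p = 0.44 with an estimated correlation). Nfkbiz, which encodes a nuclear regulator of NF-κB, was 1.70-fold lower (limma, adjusted p = 0.0182). Hp, which encodes the acute-phase protein haptoglobin, was 2.27-fold lower and the only called member of 15 STAT3 response genes in the main fit (limma, adjusted p = 0.0317; camera for the list, adjusted p = 0.0028; adjusted p = 0.44 with an estimated correlation). Leaving out iCAF replicate 3 gave 5 members called lower, Cebpd, Junb, Cebpb, Hp and Bcl3. The fibroblast index of iCAF minus that of qPSC libraries was -0.891 log2 units. Of the 15 fibroblast genes, 14 were negative and 0 called, with or without iCAF replicate 3. Their median was -1.02 (camera, adjusted p = 0.00076, and 0.50 with an estimated correlation). Of 16 iCAF marker genes, 15 were negative and 0 called, against 2 lower without iCAF replicate 3. Their median was -0.71 (camera, adjusted p = 8.1e-05, and 0.40 with an estimated correlation), and 11 belong to other lists too. Il6 lay at 0.738 ± 0.523 TPM in iCAF and 2.96 ± 0.365 TPM in qPSC libraries and did not pass with all libraries (limma, adjusted p = 0.118, and 0.0399 without iCAF replicate 3, from 0.0397 to 0.426 over the alternatives), nor did Cxcl1 (limma, adjusted p = 0.351).

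Several other lists, from antigen presentation to early-response genes, held 1 or 2 called members each in the main fit. Cd274, which encodes the immune checkpoint ligand PD-L1, lay at 9.91 ± 1.54 TPM in iCAF and 18.8 ± 1.38 TPM in qPSC libraries (limma, adjusted p = 0.0478, from 0.0286 to 0.277 over the alternatives). It was the 1 called member of 18 antigen presentation genes, of which 9 were lower when adjusted over the list alone (median -0.29; camera, adjusted p = 0.0047; adjusted p = 0.48 with an estimated correlation). These numbers were 3 and 12 without iCAF replicate 3. Vegfa and Ddit4, both induced by low oxygen, were 1.69-fold and 1.51-fold lower (limma, adjusted p = 0.0357 and 0.0443), but the 21 hypoxia genes as a list did not pass (camera, adjusted p = 0.22). The list passed without iCAF replicate 3, with 3 members called lower (camera, adjusted p = 0.023; adjusted p = 0.63 with an estimated correlation). Spry2, a feedback inhibitor of receptor tyrosine kinase signalling, was 1.75-fold lower and the 1 called member of 19 Ras and MAPK response genes, against 5 without iCAF replicate 3 (limma, adjusted p = 0.0146; camera for the list, adjusted p = 0.00037; adjusted p = 0.44 with an estimated correlation). Chac1, an integrated stress response gene, was 1.75-fold lower and the 1 called of 20 unfolded protein and stress response genes (limma, adjusted p = 0.0146; 2 called lower without iCAF replicate 3). Btg2 and Egr3, the 2 called of 18 early-response genes, were 1.85- and 1.71-fold lower (limma, adjusted p = 0.0410 and 0.0283), with 5 called lower without iCAF replicate 3. The list passed only without that library (camera, adjusted p = 0.083 and 0.00027, and 0.63 and 0.32 with an estimated correlation). It was fixed as a list of early genes tied to handling, and holds Nr4a1. The cells were released with collagenase and sorted. An effect of handling on these genes, or on Nr4a2 and Nr4a3, was not tested. Of the 24 lists that passed camera, 14 lay lower and 10 higher than the other genes, and 0 passed with an estimated correlation (adjusted p of at least 0.40). Ribosomal protein genes, 1 of the 10, had a median of 0.19 in the main comparison and 0.04 without iCAF replicate 3 (camera, adjusted p = 2.3e-19 and 0.0018; adjusted p = 0.44 and 0.58 with an estimated correlation).

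The number of called genes depended on single libraries. Without iCAF replicate 3, limma called 163 lower and 13 higher genes, including all 70 of the main comparison. Leaving out qPSC replicate 1, 2 or 3 left 0 calls, iCAF replicate 1 left 4 lower, myCAF replicate 1 left 33 and myCAF replicate 3 left 23. Leaving out iCAF replicate 2 gave 187 lower and 7 higher and myCAF replicate 2 gave 105 lower and 2 higher. Centring each library on its median moved the median fold change of all genes from -0.15 to 0.05, left 23 lower and 1 higher, and changed the 228 higher and 1623 lower genes at an unadjusted p under 0.05 to 1372 higher and 945 lower.

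The second comparison asked how tumour cells differed after co-culture with myofibroblast-like cells from those with quiescent ones. No gene passed the threshold by limma, while 312 genes were higher and 441 lower at an unadjusted p under 0.05. limma-voom on the implied reads also called 0 genes, while limma on only the 6 libraries of these groups called 158 higher and 224 lower. The 10 genes with the smallest p, which did not pass (limma, adjusted p from 0.0683 to 0.0760), were 8 with lower and 2 with higher values in myCAF libraries. They included Tgtp1 and Tgtp2, interferon-inducible GTPases whose sequences are near-copies so that reads may be shared between them, at 12.1 ± 2.68 and 18.6 ± 4.33 TPM in myCAF against 32.4 ± 1.58 and 39.96 ± 0.899 TPM in qPSC libraries (SD, n = 3). Slfn2 lay at 24.7 ± 3.31 against 54.2 ± 0.642 TPM, Ifit1 at 290 ± 63.6 against 525 ± 11.5 TPM, and Ifi209 and Ifi213 of the Ifi200 family at 2.57 ± 0.437 against 7.07 ± 0.466 and 0.533 ± 0.162 against 1.86 ± 0.0810 TPM. Ms4a4d lay at 24.4 ± 3.33 against 47.4 ± 1.61 TPM and Lcn2, an iron-binding acute-phase gene, at 53.9 ± 4.15 against 97.2 ± 4.58 TPM. Tuba1a, an alpha-tubulin gene, at 1079 ± 33.1 against 752 ± 46.2 TPM, and Acss2, which makes acetyl-CoA from acetate, at 22.7 ± 2.61 against 11.8 ± 1.18 TPM, had higher values in myCAF libraries.

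As lists, interferon and antigen presentation genes were lower after myCAF co-culture by camera at the preset correlation, but not by fry (adjusted p = 0.084 for each). Of 25 interferon-response genes, 0 passed over all genes (10 lower without iCAF replicate 3). When adjusted over the list alone 18 were lower, and 24 were negative, with a median log2 fold change of -0.46 (camera, adjusted p = 6.3e-28; adjusted p = 0.18 with an estimated correlation). Of 18 antigen presentation genes, 0 passed over all genes (4 lower without iCAF replicate 3) and 7 were lower when adjusted over the list alone, among them H2-D1, H2-K1 and Tap1, with a median of -0.37 (camera, adjusted p = 2.6e-11; adjusted p = 0.18 with an estimated correlation). H2-K1, a major histocompatibility class I gene, lay at 1116 ± 45.8 TPM in myCAF and 1515 ± 68.4 TPM in qPSC libraries. Genes named here as passing over a list alone were chosen after their values were seen, as those with small p in their list.

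Several metabolic lists were higher after myCAF co-culture by camera at the preset correlation. Those of oxidative phosphorylation, the TCA cycle, fatty acid oxidation and the pentose phosphate pathway with nucleotide synthesis did not pass (camera, adjusted p = 0.39, 0.14, 0.17 and 0.95). With fry 0 lists passed in this comparison. Its adjusted p was 0.084 for cholesterol synthesis, 0.17 for hypoxia, 0.26 for glycolysis and 0.36 for serine and amino acid synthesis. All 24 cholesterol synthesis genes had positive fold changes, with 12 higher when adjusted over the list alone, 0 over all genes and a median of 0.27 (camera, adjusted p = 5.0e-21; adjusted p = 0.18 with an estimated correlation). Mvd, of the mevalonate pathway, lay at 267 ± 10.6 against 198 ± 8.73 TPM, and Hmgcs1 at 625 ± 26.9 against 490 ± 37.4 TPM. In iCAF against qPSC the cholesterol list also lay higher than the other genes, with a median of -0.015 and 0 called (camera, adjusted p = 0.00042, and 0.48 with an estimated correlation). Without iCAF replicate 3 that median was 0.10, with 1 gene, Nsdhl, called higher. All 13 fatty acid synthesis genes were positive in myCAF against qPSC, with 0 called and 4 without iCAF replicate 3 (camera, adjusted p = 2.7e-05, and 0.46 with an estimated correlation). Of 21 hypoxia genes, 9 were higher when adjusted over the list alone and 19 were positive (median 0.46; camera, adjusted p = 4.6e-14; adjusted p = 0.26 with an estimated correlation), with 0 over all genes and 2, Bnip3l and Ero1l, without iCAF replicate 3. Ndrg1, 1 of the 9, lay at 332 ± 31.3 against 222 ± 29.0 TPM. Of 16 glycolysis genes, 9 were higher and 1 lower when adjusted over the list alone, with 0 over all genes and 1 higher and 1 lower without iCAF replicate 3 (median 0.22; camera, adjusted p = 1.2e-08; adjusted p = 0.33 with an estimated correlation). Serine and amino acid synthesis genes had a median of 0.18, with 5 of 21 higher when adjusted over the list alone, such as Asns and Psat1, 0 over all genes and 7 without iCAF replicate 3 (camera, adjusted p = 1.0e-07; adjusted p = 0.39 with an estimated correlation). The 20 genes of the unfolded protein and integrated stress responses had a median of 0.15, with 3 higher when adjusted over the list alone, Hspa5, Hsp90b1 and Pdia6, all of the endoplasmic reticulum, 0 over all genes and 3 without iCAF replicate 3 (camera, adjusted p = 9.2e-08; adjusted p = 0.18 with an estimated correlation). The 15 fibroblast genes had a median of 0.25, with 0 called and 2 higher without iCAF replicate 3, and the fibroblast index was higher by 0.41 log2 units in myCAF than in qPSC libraries.

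Without iCAF replicate 3, which belongs to neither group but enters the shared estimate of the spread, limma called 121 genes higher and 210 lower in myCAF than in qPSC libraries, among them 13 cholesterol synthesis genes and all 10 of the genes named above. Leaving out iCAF replicate 2 gave 9 lower, myCAF replicate 2 gave 4 higher and 18 lower, and myCAF replicate 3 gave 1 lower, while leaving out another library gave 0. Krt19, a ductal keratin, lay at 42.0 ± 4.38 TPM in myCAF and 15.8 ± 4.63 TPM in qPSC libraries (limma, adjusted p = 0.268, and 0.0303 without iCAF replicate 3, from 0.019 to 0.84 over the alternatives). Acta2, which encodes smooth muscle actin, a myofibroblast marker, lay at 6.02 ± 1.51 against 2.64 ± 0.595 TPM (limma, adjusted p = 0.209, and 0.0282 without iCAF replicate 3, from 0.0263 to 0.733 over the alternatives). Of the 12 tested genes in the list of myofibroblast markers, 7 were positive and 5 negative, with 0 called (camera, adjusted p = 0.015, and 0.47 with an estimated correlation). Without iCAF replicate 3, 2 were called higher, Postn and Acta2, and 1 lower, Tgfb1.

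**Figure D3:**
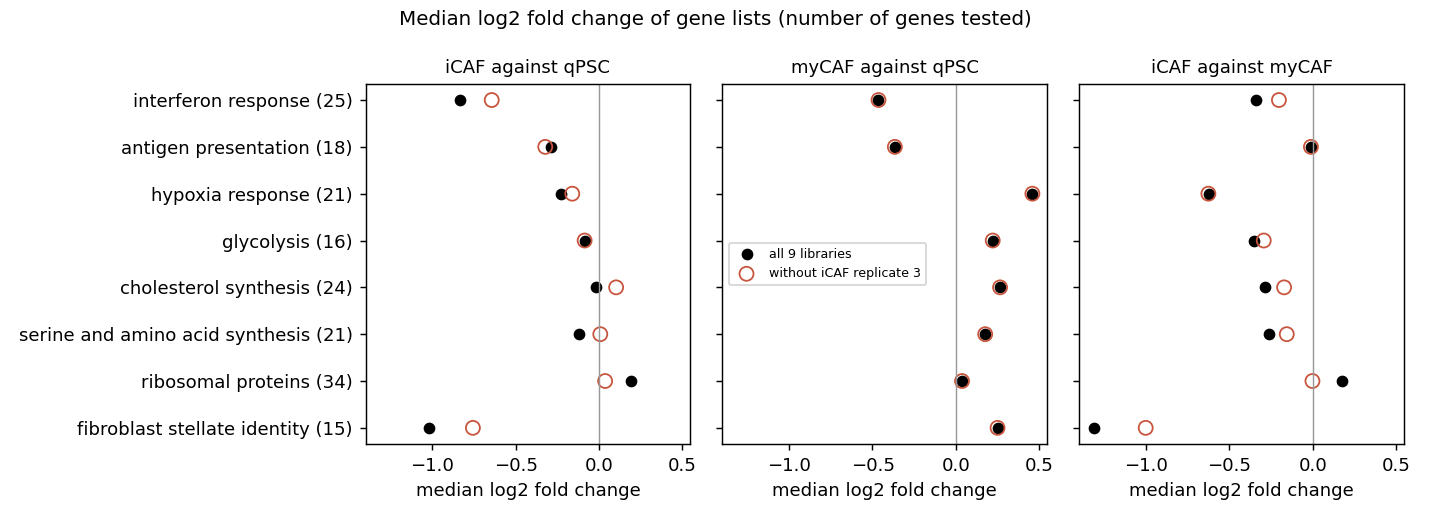
Median log2 fold change (horizontal axis) of 8 gene lists (vertical axis, with the number of genes tested) in the 3 comparisons. Filled points use all 9 libraries and open circles leave out iCAF replicate 3; the interferon list lies at -0.83 and -0.46 against qPSC, and the ribosomal protein list moves from 0.19 to 0.04 in iCAF against qPSC.

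The third comparison set the inflammatory against the myofibroblast-like co-cultures. By limma, 7 genes were lower and 0 higher after iCAF than after myCAF co-culture, with 284 genes higher and 1814 lower at an unadjusted p under 0.05. Centring each library on its median left 0 calls and turned these to 1613 higher and 1093 lower. Postn, which encodes the matrix protein periostin, lay at 0.0810 ± 0.0625 TPM in iCAF and 10.0 ± 5.02 TPM in myCAF libraries, a log2 fold change of -3.23 ± 0.33 (SE) on the log2(TPM + 1) scale (limma, adjusted p = 0.0325). Postn is a fibroblast and myofibroblast marker, and the fibroblast index of iCAF minus that of myCAF libraries was -1.297 log2 units. The other 6 shared a limma adjusted p of 0.0474. Tnfrsf9, which encodes the co-stimulatory receptor 4-1BB, lay at 34.0 ± 8.24 against 94.2 ± 10.8 TPM. Txnip and Arrdc3, both of the arrestin family, were 2.16- and 2.00-fold lower, Cth, an enzyme of cysteine synthesis, was 2.08-fold lower, Vegfa was 1.87-fold lower and Fam110c was 1.79-fold lower. Postn lies on chromosome 3 from 54361109 to 54391037 and Vegfa on chromosome 17 from 46016993 to 46032369 in GENCODE M21 (GRCm38).

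**Figure D4:**
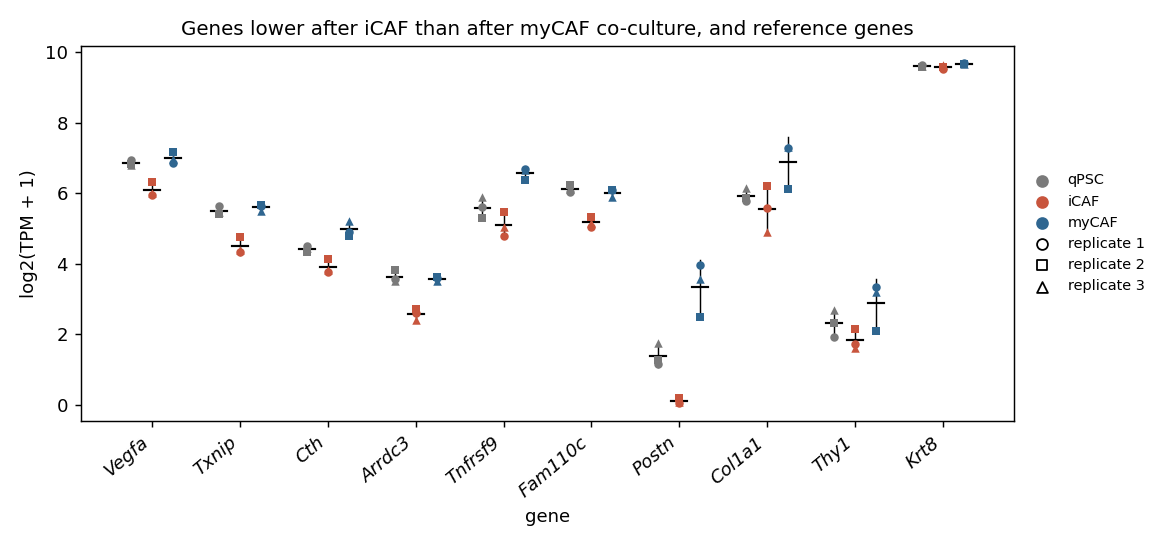
Expression of the 7 genes called lower in iCAF than in myCAF libraries, with Col1a1, Thy1 and Krt8 for reference, as log2(TPM + 1) on the vertical axis for each gene on the horizontal axis. Points are libraries, short bars are group means and vertical lines are ± 1 SD of 3 libraries; Tnfrsf9 averages 34.0 TPM in iCAF and 94.2 TPM in myCAF libraries.

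Hypoxia, glycolysis and cholesterol synthesis genes were lower as lists after iCAF than after myCAF co-culture. The median log2 fold change of all genes in this comparison was -0.15, and -0.03 without iCAF replicate 3. The medians, signs and counts over a list alone below include that shift. All 21 hypoxia genes were negative, 15 were lower when adjusted over the list alone and 1, Vegfa, over all genes, against 3 without iCAF replicate 3 (median -0.62; camera, adjusted p = 7.2e-10; adjusted p = 0.65 with an estimated correlation; fry, adjusted p = 0.041). Ero1l, an oxidase of the endoplasmic reticulum, lay at 122 ± 43.4 TPM in iCAF and 291 ± 59.4 TPM in myCAF libraries. All 16 glycolysis genes were negative, with 14 lower when adjusted over the list alone and 0 over all genes, with or without iCAF replicate 3 (median -0.35; camera, adjusted p = 2.6e-06; adjusted p = 0.65 with an estimated correlation). Slc2a1, a glucose transporter gene, lay at 181 ± 34.6 against 281 ± 19.8 TPM. Of 24 cholesterol synthesis genes, 23 were negative, 7 were lower when adjusted over the list alone and 0 over all genes, against 1 without iCAF replicate 3 (median -0.29; camera, adjusted p = 0.00019; adjusted p = 0.65 with an estimated correlation). The 15 fibroblast genes were all negative with a median of -1.31, 14 were lower when adjusted over the list alone and 1, Postn, over all genes, with or without iCAF replicate 3 (camera, adjusted p = 2.3e-07; adjusted p = 0.65 with an estimated correlation). Interferon-response genes had a median of -0.34, with 6 of 25 lower when adjusted over the list alone and 0 over all genes, against 1 without iCAF replicate 3 (camera, adjusted p = 0.00097; adjusted p = 0.65 with an estimated correlation).

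Without iCAF replicate 3, limma called 56 genes lower and 14 higher in this comparison, including all 7, and without iCAF replicate 2 it called 272 lower and 7 higher. Leaving out myCAF replicate 2 gave 279 lower and 2 higher, iCAF replicate 1 gave 1 lower, myCAF replicate 3 gave 1 lower and 1 higher, and leaving out myCAF replicate 1 or any qPSC library gave 0.

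The overlap of the calls against the shared qPSC libraries was counted with all libraries and without iCAF replicate 3. With all libraries, 0 genes were called in both comparisons, which was fixed by the 0 calls for myCAF against qPSC. With that library left out, 62 genes were lower and 5 higher in both, where independent lists would share 2.93 and 0.14 and simulated unchanged groups shared 0. The covariance of the log2 fold changes was 0.014 against 0.0176 in simulated unchanged groups with all libraries, and 0.0138 against 0.0085 without iCAF replicate 3. The simulation gave every library the pooled spread of a gene, which iCAF replicate 3 widens. The simulated covariance with all libraries may therefore overstate what the qPSC libraries alone would give. The correlation was 0.276 against 0.501 and 0.325 against 0.45. Fold changes had the same sign in 54.8% of genes against 66.7% and in 61.5% against 64.8%, so each lay below its simulated value. The 3 qPSC libraries were not split between the comparisons, so part of the shared calls may come from the shared controls. The simulated number leaves out the effects and the independent one leaves out the shared controls, so neither shows how many changes are shared.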

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

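The additions after seeing the data were limma-voom, removal of the gene-length trend, all fits that leave out iCAF replicate 3 together with another change, and the overlap without iCAF replicate 3. The count models planned for raw counts were not run, because the values are TPM. Where no reason is given, the cause was not tested.

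For iCAF against qPSC, the main 70 lower and 0 higher genes became 34 lower at an absolute log2 fold change of at least 1, 23 lower and 1 higher with median centring, 33 and 1 with upper-quartile centring, 5 lower with no filter, where more genes are tested, 37 with only the 6 libraries, 33 with limma-voom, and 99 lower and 5 higher with the length trend removed. Counts stayed within 1.5 times with the strict filter (48), pseudocount 0.1 (69) and no trend (53). With iCAF replicate 3 left out, they were 88 lower and 15 higher with median centring, 132 and 15 with limma-voom, 131 and 17 with the length trend removed, and 157 and 24 with the fibroblast covariate. Leaving out each library gave from 0 to 187 lower and from 0 to 13 higher.

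For myCAF against qPSC, the main 0 and 0 became 1 higher with no filter, 158 higher and 224 lower with only the 6 libraries, and 9 and 29 with the length trend removed. With iCAF replicate 3 left out, they were 143 higher and 204 lower with median centring, 145 and 196 with limma-voom, 174 and 239 with the length trend removed, and 146 and 350 with the fibroblast covariate. Leaving out each library gave from 0 to 121 higher and from 0 to 210 lower.

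For iCAF against myCAF, the main 7 lower became 0 with median centring, the strict filter, the 6 libraries or limma-voom, 1 with no filter, pseudocount 0.1 or no trend, 2 with upper-quartile centring, and 41 lower with 5 higher with the length trend removed. With iCAF replicate 3 left out, they were 32 lower and 20 higher with median centring, 52 and 18 with limma-voom, 61 and 18 with the length trend removed, and 10 and 10 with the fibroblast covariate. Leaving out each library gave from 0 to 279 lower and from 0 to 14 higher. The overlap of calls against qPSC was 0 in the main fit and 67 genes without iCAF replicate 3.

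With the replicate block, iCAF against qPSC had 22 lower genes and iCAF against myCAF had 0. With iCAF replicate 3 left out as well, the block gave 86 lower and 1 higher for iCAF against qPSC, 10 higher and 56 lower for myCAF against qPSC, and 9 lower for iCAF against myCAF. Of 9 pairs of libraries with the same number, 2 had a correlation of deviations over 0.1, from -0.353 to 0.248, so the numbers are not taken to pair samples.

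Of 38 lists, 24, 19 and 18 passed with camera for iCAF against qPSC, myCAF against qPSC and iCAF against myCAF. With an estimated correlation 0 passed in each, and fry passed 13, 0 and 9. Leaving out each library gave from 13 to 28, from 17 to 22 and from 13 to 20. The lowest for iCAF against qPSC, 13, came without iCAF replicate 1.

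No gene named by the rule and called in the main fit turned its direction. Counting each gene in each alternative setting, the 20 called for iCAF against qPSC stayed past the threshold in 271 of 475 values. The 7 for iCAF against myCAF did in 55 of 166 values. Marker genes that did not pass turned their sign at these log2 values. With the fibroblast covariate and without iCAF replicate 3, the values for iCAF against qPSC were Thy1 0.423, Col1a1 0.728 (limma, adjusted p = 0.0193, with Col1a1 itself part of the index), Cxcl1 0.413 and Mki67 0.018. Under the same setting they were Il6 -0.003 and Cxcl1 -0.227 for myCAF against qPSC, and Thy1 0.339, Col1a1 0.227, Vim -0.016, Cxcl1 0.640 and Mki67 0.001 for iCAF against myCAF. Col1a1 for iCAF against qPSC was 0.020 with median centring, 0.118 with the block and 0.002 with the length trend removed, all without iCAF replicate 3. Krt8 for iCAF against qPSC was 0.174 with median centring, 0.122 with upper-quartile centring, 0.152 with limma-voom, 0.015 with the length trend removed and 0.011 with median centring without iCAF replicate 3. Krt8 for iCAF against myCAF was 0.113, 0.037 and 0.085 with median centring, upper-quartile centring and limma-voom. With each library left out, Krt8 for iCAF against qPSC ranged from -0.047 to 0.001, Acta2 from -0.028 (without iCAF replicate 2) to 0.288, and for myCAF against qPSC Il6 from -0.185 to 0.349 and Cxcl1 from -0.137 to 0.702, both lowest without myCAF replicate 1.

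The 6 libraries of a comparison make 10 splits of 3 against 3, too few for a share under 0.05, and 1 split, the real one, reached the real value wherever it was above 0. For iCAF against qPSC the real split called 70 genes and the highest other 1, with 24 lists against 20. For myCAF against qPSC they called 0 and 0 genes, so that all 10 splits gave as many, and 19 lists against 15. For iCAF against myCAF they called 7 and 0 genes, and 18 lists against 14.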

Other observations

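The gene families and the tests of explanations in this part were chosen after the results were seen. The 10 tested genes of the Ifi200 family were all negative in iCAF against qPSC, with 6 called lower and a median log2 fold change of -1.11, and all negative in myCAF against qPSC, with 0 called and a median of -0.69. In these 2 comparisons 6 and 5 of them were called lower without iCAF replicate 3. Of 13 interferon-inducible GTPase genes (Gbp, Irgm, Iigp1, Igtp and Tgtp), 5 were lower in iCAF than in qPSC libraries with a median of -0.87, and all 13 were negative in myCAF against qPSC with a median of -0.63. Of these GTPase genes, 10 and 9 were called lower without iCAF replicate 3. The 3 Nr4a genes had a median of -2.14 in iCAF against qPSC, with 2 called lower and 3 without iCAF replicate 3, and -0.18 in myCAF against qPSC. Reads of several members may be shared between near-copies, which the whole-read steps at 97.8% of genes cannot show, and the values of single members are uncertain for that reason.

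The 2 lists of cell cycle genes gave no called member with all libraries, and without iCAF replicate 3 only Tpx2, a spindle gene, was called, higher in myCAF than in qPSC libraries (log2 fold change 0.183; limma, adjusted p = 0.0474). The 23 genes of the G1/S phase had a median of -0.06 in iCAF against qPSC and 0.01 in myCAF against qPSC, and the 24 mitosis genes -0.01 and 0.10. Relative to the other genes, both lists lay higher in iCAF against qPSC (camera, adjusted p = 0.017 and 0.0044; adjusted p = 0.64 and 0.56 with an estimated correlation). In myCAF against qPSC the mitosis list did (camera, adjusted p = 0.0034; adjusted p = 0.61 with an estimated correlation), and the G1/S list did not pass. Oxidative phosphorylation genes had a median of 0.12 in iCAF against qPSC, with 0 of 37 called, and 0.06 without iCAF replicate 3 (camera, adjusted p = 5.2e-14 and 0.0021; adjusted p = 0.40 and 0.36 with an estimated correlation).

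The position of iCAF replicate 3 went with gene length. Across genes, its deviation from the other iCAF libraries fell with exon length, with a Spearman rho of -0.616 (genes are not independent replicates). The largest rho in the other 8 libraries was 0.514, in iCAF replicate 2, whose comparison includes replicate 3. Depth is not a likely cause, since the 44563193 implied reads of this library lay inside the range of the other libraries. Nor is a lower level of the fibroblast genes, since iCAF replicate 1, with an index within 0.5 of it, had a ribosomal protein share of 15.501%. A bias towards short transcripts in this library may explain its position, while a difference between the cultures stays open and was not tested.

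The 15 tested fibroblast genes rose and fell together within groups over 8 libraries, with a median pairwise correlation of 0.889, where the 95th percentile of 2000 random lists matched on expression was 0.261. Fibroblasts carried over in different amounts through the sort would give this, and so would a shared programme of the tumour cells. The most abundant were Sparc, Dcn and Col1a1, at 236, 133 and 127 TPM in myCAF and 202, 34.7 and 49.6 TPM in iCAF libraries. Cultured fibroblasts are known to hold abundant Col1a2, Lum and Tagln transcripts too, yet the highest value of these 3 genes in a library was 0.745 TPM, while Col1a1 differed by 77.2 TPM between the means of myCAF and iCAF libraries. This argues against carried-over fibroblasts as the main source of the difference, although the stellate cells themselves were not measured here. A programme of the tumour cells stays open and was not tested.

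Lower interferon genes after both primed co-cultures were weighed against these patterns. Both comparisons used the same qPSC libraries, so they are not independent, and a shift of these libraries would lower the list in both. The qPSC cells were also the only ones that had not been primed. Neither point was tested. Without iCAF replicate 3 the median of the list in iCAF against qPSC minus that of all genes was -0.612, which argues against that library as the whole cause. With the fibroblast index as a covariate and without iCAF replicate 3, the list kept a median of -0.806 in iCAF against qPSC, with 19 of 25 members called lower, and of -0.398 in myCAF against qPSC, with 10 called lower. This argues against the level of the index genes as the whole cause in myCAF against qPSC. For iCAF against qPSC it cannot decide. The remaining iCAF libraries had indices of 3.796 and 4.315, below all qPSC libraries (4.523 to 4.903), so the fit extrapolates. Neither value decides on the amount of fibroblast RNA, since the low Col1a2, Lum and Tagln values speak against the index following that amount. The index itself was higher by 0.406 in myCAF than in qPSC libraries, but inside its spread (exact permutation test, p = 0.4). Interferon transcripts from carried-over fibroblasts of a different state were not tested directly. The values of Col1a2, Lum and Tagln, at most 0.745 TPM in a library, argue against much fibroblast RNA, with the limit that the stellate cells were not measured. Weaker interferon signalling in the tumour cells after co-culture with primed fibroblasts is a hypothesis that no test here decides.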
